A study of Saccharomyces cerevisiae with 267 samples.

How the data were processed

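Transcript levels were measured by RNA sequencing in 267 libraries of Saccharomyces cerevisiae BY4743, a diploid laboratory strain made by crossing haploid derivatives of S288C. Of these, 266 libraries came from 238 heterozygous strains, each with a green fluorescent protein (GFP) cassette driven by the RPL5 promoter in place of one allele of a named gene, called the target here, and 1 library came from the wild type. Per the labels' protocols, each strain was grown overnight in rich glucose medium, total RNA was taken with a column kit, and libraries were made with the standard kit of the sequencer's maker. Whether the libraries kept strand is not given in the sources used here.

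Per the submitters' processing notes, reads were trimmed with Trimmomatic, aligned with HISAT2 and quantified with StringTie, on the R64 build; their versions and settings are not given in the sources used here. Each library has a gene abundance table with 7124 entries, 7123 genes and GFP. Per the file headers, the tables hold the coverage, the FPKM (fragments scaled by gene length and library size) and the TPM (transcript share scaled to a fixed library total) of each gene. The deposited TPM was the measure analysed, since it was already scaled to the same total in each library. The deposited coverage, which is a signal of mean read depth along a gene, and the deposited FPKM served only to estimate depth: their ratio gives the aligned bases behind a table. The TPM of a library summed to 994362 to 999373. No count of reads is in the tables used here, so no count model was fitted and no counting interval is given.

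Samples were grouped by the genotype in the labels, and targets were found in the tables by symbol for all 238 strains. The first number of a library title, 1 to 6, was used as a batch-like prefix, although no label says what it marks. It largely followed the chromosome of the target: mostly I in prefix 1, VI in 2 and IV in 3. Targets of prefix 4 lay on VIII, XV or XVI and those of prefix 5 on X to XIV. Effects of the prefix and of the insertion chromosome can therefore not be fully separated. Libraries with prefixes 1 to 6 numbered 44, 25, 30, 55, 74 and 38, from 34, 25, 30, 55, 74 and 20 strains. The wild type carries no such prefix. Of the strains, 220 had 1 library, 13 had 2, 2 had 3, 2 had 4 and 1 had 6. No label says whether libraries of a strain came from separate cultures, so p-values measure only the spread between these libraries and strains, which may be technical. No library held values identical to another, and the highest correlation of log2(TPM + 1) between 2 libraries was 0.988.

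The deviation of a gene in a library was log2(TPM + 1) minus the median over reference strains, minus the library's median deviation. Reference strains were the GFP strains of the same prefix, without the strain itself and without strains whose target lay within 50 kb of the gene. A strain's value was the mean over its libraries, and z was the deviation divided by the scaled median absolute deviation of the reference strains. Fold changes and deviations are on the log2(TPM + 1) scale, which understates changes of weakly expressed genes. Genes with a median TPM of 5 or more were tested, 5983 genes in all, and 231 of the 238 targets passed. Means of strain values were tested against 0 by two-sided sign-flip permutation, differences and correlations by two-sided label permutation, each with 100000 resamples, and neighbours also against 10000 draws of the same genes in strains of the same prefix inserted elsewhere. The 11 tests at and around the insertion were adjusted together by Benjamini-Hochberg.

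Gene order and coordinates came from the deposited tables. Of 6047 gene IDs shared with the reference table for the R64 build, 6018 (99.5%) had the same start and end. Adjacent genes were the nearest genes that did not overlap the target, with sides taken relative to the target's strand. A divergent neighbour is transcribed away from the target, a convergent one towards it and a tandem one in the same direction. Sequences lost or added by the cassette were not analysed here.

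Strains with 3 or more libraries, all of prefix 6, were compared with the other prefix-6 libraries, strains of prefix 1 with 2 libraries were compared by an F test, and strains with targets in the ribosome, transcription machinery, splicing or mitochondrion class were compared with all other GFP strains with the prefix as a factor. These fits used limma (eBayes with trend) on log2(TPM + 1) with Benjamini-Hochberg adjustment and a threshold of 0.05. Camera with a preset correlation of 0.01, camera with an estimated correlation and fry tested fixed gene lists: ribosomal proteins, ribosome biogenesis, environmental stress response, chaperones, respiratory chain, tricarboxylic acid (TCA) cycle, fatty acid oxidation, glycolysis, hexose transport, sulfur amino acids, amino acid biosynthesis, ergosterol, purines, phosphate, iron, histones, haploid a-specific, haploid-specific, meiosis and auxotrophic markers. Lists of alpha-specific and mitochondrially encoded genes had fewer than 3 members above the TPM minimum and were not tested. The wild type, with 1 library, was compared without a test. The same list medians were taken in each GFP library against the strains other than its own, a step chosen after the values were seen.

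The tests, lists, classes and most alternatives were fixed before the data were examined, as was the rule for named genes. It takes the 10 lowest and 10 highest targets, every target not lowered (above -0.5) and every replicated strain; the 10 highest and lowest adjacent genes beyond 3 scaled median absolute deviations; up to 12 genes each way with adjusted p under 0.05 and median TPM of 10 or more in limma comparisons, with 2 to 4 past the threshold per list; 10 each way for the wild type, with auxotrophic markers and RPL5; and the 3 highest and lowest paralogs, complexes and pathways. Alternatives were other pseudocounts (0.1 and 5), TPM minimums of 1 and 20 or none, all-prefix references, no library centring or added centring, removal of 5 principal components, no prefix term, array weights, genotype as a factor, the first library of each strain alone, strains without prefix 6, and each replicate left out.

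Prefix-1 titles number the 2 libraries of a strain 1 and 2. Deviations of same-numbered libraries from their strain means had a mean correlation of -0.013 over 45 pairs of strains (lowest -0.37, highest 0.19), and 7 pairs were above 0.1, so the numbers were not treated as a pairing. The steps were tested on simulated data made from the gene means and spreads of the real tables, with noise drawn separately for each gene. Genes in the real data vary together, so the recovery below does not measure power or false calls there. A planted target change of -1 was recovered as -1.00. For limma, 80 genes were changed by 0.5, 80 by 1 and 40 by 2 on the log2 scale among 5983, and 4 to 12 unchanged genes were called. In the PAN5, NNF2, SWH1, TRM13 and FRS2 comparisons it recovered 37.5%, 27.5%, 26.3%, 21.3% and 22.5% of those changed by 0.5, and 86.3%, 78.8%, 75%, 71.3% and 73.8% of those changed by 1. In the ribosome, transcription machinery, splicing and mitochondrion comparisons it recovered 88.8%, 71.3%, 62.5% and 78.8% of those changed by 0.5. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.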

Results

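The study asked how the same reporter, inserted separately at many loci of the yeast genome, changes the levels of transcripts around it and elsewhere. The 267 libraries comprised 266 from 238 GFP strains and 1 from the wild type. Estimated from coverage and FPKM, a library rested on 519 to 1302 megabases of aligned sequence (median 1190), and the wild type on 617 megabases. Between 6512 and 6722 genes had a TPM above 0. Ribosomal DNA transcripts took a median of 5.44% of TPM (0.598% to 46.4%), with the highest share in the YTH1 strain, library 2.

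The reporter itself was read first as a check of the labels. GFP stood at 0.019 TPM in the wild type and at 255.9 TPM or more in every GFP library, with a median of 555 TPM over strains. The IMP4 strain was the highest at 5129 TPM. The SD between strains, centred by prefix, was 0.48 on the log2 scale (0.44 without IMP4), against 0.26 between libraries of 1 strain over 18 replicated strains. GFP was not related to the expression of the target (r = 0.033, p = 0.61; rho = 0.045, p = 0.48; r = 0.038 without the 2 farthest strains), to the distance from the telomere (r = 0.079, p = 0.22; rho = 0.067, p = 0.30; r = 0.055) or to the expression of the neighbours (r = -0.022, p = 0.73; rho = -0.060, p = 0.36; r = -0.029), over 238 strains by permutation. Adjusted p over these 3 relations was 0.67 or higher for r and 0.48 for each rho, and r within prefixes ran from -0.12 to 0.15, from -0.12 to 0.24 and from -0.26 to 0.15.

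Replacing one allele lowered the target transcript. The mean deviation of the target in its own strain was -0.89 ± 0.47 (SD, n = 231), which is 0.539 times the level in the other strains, and 222 of 231 targets lay below 0. The lowest were IME1, the master activator of meiosis (YJR094C, X:604569-605651, -2.27), ALR1, a magnesium transporter (-2.18), YAH1, the mitochondrial ferredoxin (-2.11), and ATX1, a copper chaperone (-2.11). They were followed by RPO41, the mitochondrial RNA polymerase (-1.93), FUN12 (-1.89 ± 0.07, n = 2), MRP2 (-1.82), SPC72 (-1.79), ESC1 (-1.77) and BBC1 (-1.70). Between -1.5 and -0.5 lay 175 targets, 19 were lower, and the quartiles were -1.15 and -0.65. By sign-flip permutation the mean differed from 0 (p = 1e-05, the smallest these permutations can give; adjusted p = 0.00011). Means by prefix were -1.03, -0.88, -0.85, -0.85, -0.90 and -0.80, and 105 targets had a z of -3 or less.

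**Figure D1:**
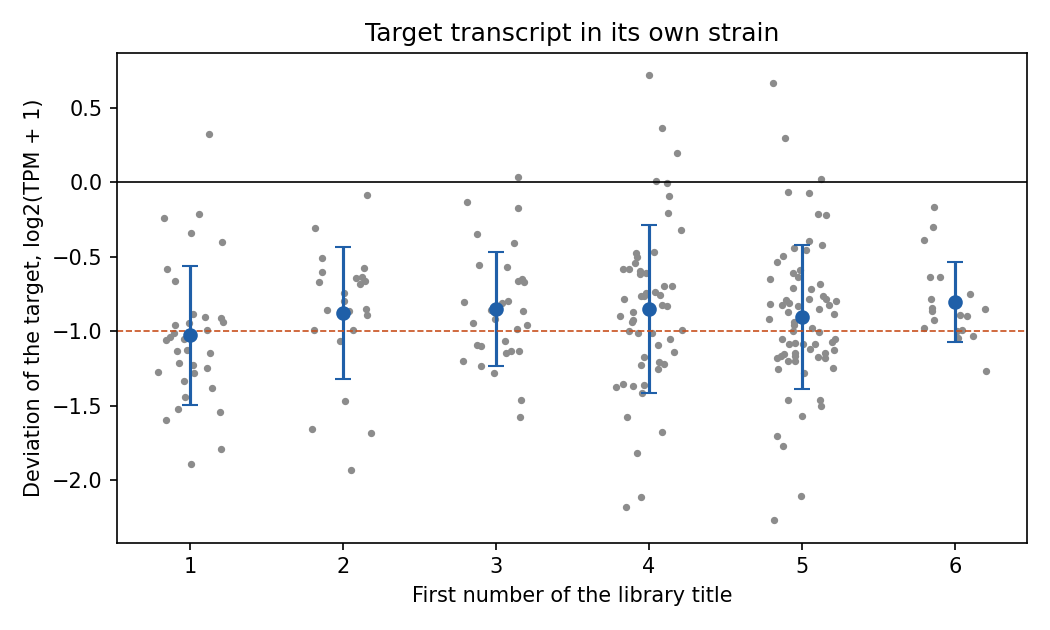
Deviation of the target transcript in its own strain, as log2(TPM + 1) relative to strains of the same title prefix, by the first number of the library title. Grey points are strains, blue points and bars are the mean and SD, and the dashed line marks -1; the prefix means run from -1.03 to -0.80.

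In 37 of the 231 strains the target counted as not lowered, with a deviation above -0.5. Of these, 22 were above -0.25 and 9 above 0. For 1 of the 37, INO1, the other genes of its chromosome were also high (0.42). None of the 37 had a z of -3 or less. The highest were SMX3, a core spliceosomal Sm protein (YPR182W, XVI:900194-900454, 0.72), UTP21 of the small-subunit processome (0.66), DPM1, the dolichol phosphate mannose synthase that lies next to SMX3 (XVI:900755-901558, 0.36), GCV3 of the glycine decarboxylase (0.33), ORC5 of the origin recognition complex (0.29) and RPC82 of RNA polymerase III (0.20). PPH21 (0.03), GZF3 (0.02), GEP3 (0.01) and RPB8 (-0.01) lay at the level of the other strains. For the strains labelled with these 10 targets, the level relative to other strains gives no sign of the lost allele. Partners in the same complex were also high in the UTP21 (0.84), RPB8 (0.71) and RPC82 (0.69) strains, but not in the ORC5 (0.02) and SMX3 (-0.02) strains. Whether a shared rise hid a drop of the target was not tested. The others were SEC61 (-0.07), RPS27A (-0.08), RET2 (-0.09), NOC2 (-0.09), RPS13 (-0.13), the actin gene ACT1 (-0.17), GTO1 (-0.18), TPT1, CUE4 and HYP2 (each -0.21), COF1 (-0.22), PGS1 (-0.24), GUS1 (-0.30), PHO4 (-0.31), RPC40 (-0.32), ADE1 (-0.34), RRP1 (-0.35), IMP4 and SMD2 (each -0.39), CHO1 (-0.40), UTP5 (-0.41), EMW1 (-0.42), INO1 (-0.44), SWI3 (-0.46), NOP10 and GIC1 (each -0.47) and NET1 (-0.50). HYP2 shares its locus with the antisense gene YEL034C-A, which had -0.62 in the same strain. Reads of such a pair cannot be told apart without strand, and whether the cassette removed sequence of both genes was not analysed.

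Among the 18 strains with more than 1 library, the lowest target mean was that of FUN12 and the highest that of TRM13 (-0.63 ± 0.33, n = 3). Of the others, LTE1 (-1.60 ± 0.39), GIP4 (-1.54 ± 0.06), ACS1 (-1.21 ± 0.62), CNE1 (-1.14 ± 0.39), TPD3 (-1.04 ± 0.003), MET12 (-1.03 ± 0.12), NUP60 (-1.01 ± 0.22), CYS3 (-0.99 ± 0.25), MYO1 (-0.98 ± 0.16), KIN3 (-0.90 ± 0.15), RBG1 (-0.88 ± 0.04) and YTH1 (-0.64 ± 0.60) had SDs over 2 libraries. FRS2 (-0.9997 ± 0.46) had 3 libraries, SWH1 (-0.78 ± 0.13) and NNF2 (-0.75 ± 0.32) had 4, and PAN5 (-0.79 ± 0.33) had 6. The median SD within a strain was 0.23. The drop was not clearly related to the expression of the target: r = 0.146 (permutation p = 0.026, adjusted p = 0.073), rho = 0.115 (p = 0.079) and r = 0.145 without the 2 farthest targets. Within prefixes r was 0.16, 0.15, 0.28, 0.15, 0.03 and 0.56. A pseudocount of 5 turned the sign (r = -0.038), and with a pseudocount of 0.1 the relation passed the threshold (r = 0.202, adjusted p = 0.0076). It also passed among targets with a median TPM of 20 or more (r = 0.170, adjusted p = 0.047) and without the 24 strains with a shifted chromosome (r = 0.176, adjusted p = 0.039).

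Genes next to the insertion mostly lay near their level in other strains. Of 420 adjacent genes, 334 (79.5%) lay within 0.5 of 0. The share for the same genes in strains inserted elsewhere was not taken. Transcripts of both alleles were measured together, so a change of only the allele beside the cassette would appear diluted. The mean was 0.04 ± 0.56 (SD, n = 208) on the 5' side and 0.04 ± 0.40 (n = 212) on the 3' side. The highest adjacent gene was ANB1, the hypoxic translation factor eIF5A, in the CYC1 strain (YJR047C, X:524908-525381, 953 bp from the target, 2.69). It was followed by POL2 of DNA polymerase epsilon in the ORC5 strain (1.83), the v-SNARE gene SNC1 in the GIP4 strain (1.4999), BDH1, butanediol dehydrogenase, in the ECM1 strain (1.47), TOP2 in the TCB2 strain (0.90) and PUS5 in the SEC10 strain (0.65). The lowest were SSF1, a ribosome assembly factor, in the HTD2 strain (-2.39), MRP10 in the FAD1 strain (-1.42), the noncoding IRT1 upstream of IME1 in the IME1 strain (-1.34), the RNA helicase gene DED1 in the GEP3 strain (-1.25), LTE1 in the MAK16 strain (-1.15) and SWC3 in the CYS3 strain (-0.87). SNC1 and TOP2 lay on chromosomes whose other genes were also high in those strains, with medians of 0.89 and 0.53.

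Neither side differed from 0 by sign-flip permutation (5' p = 0.34, adjusted p = 0.54; 3' p = 0.13, adjusted p = 0.28). The 12 genes beyond 3 scaled median absolute deviations, 6 on each side of 0, compare with 12.6 expected from strains inserted elsewhere (permutation p = 0.61, adjusted p = 0.74). These were strains of the same prefix inserted on another chromosome. For the chromosome VI targets of prefix 2 they were only ORC2, TFC1 and REI1, so the draws reuse few profiles there. Over gene ranks 1 to 10 on each side and gaps up to 50 kb, 0 of 52 tests passed adjustment; 3 had an unadjusted p under 0.05, the lowest being for gaps of 1 to 2 kb, with a mean deviation of 0.11 (SE 0.04, permutation p = 0.0016, adjusted p = 0.083). Removal of the first 5 principal components, which takes out variation shared by many genes, changed these calls. The means became 0.08 on the 5' side (adjusted p = 0.0025) and 0.06 on the 3' side (adjusted p = 0.0032), 16 genes lay beyond 3 scaled median absolute deviations (adjusted p = 0.0025), and 15 of the 52 tests passed, with 0.06 at gaps up to 1 kb. Here the scaled median absolute deviation was taken over all strains and not the reference strains, so 16 and 12 are not directly comparable.

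**Figure D2:**
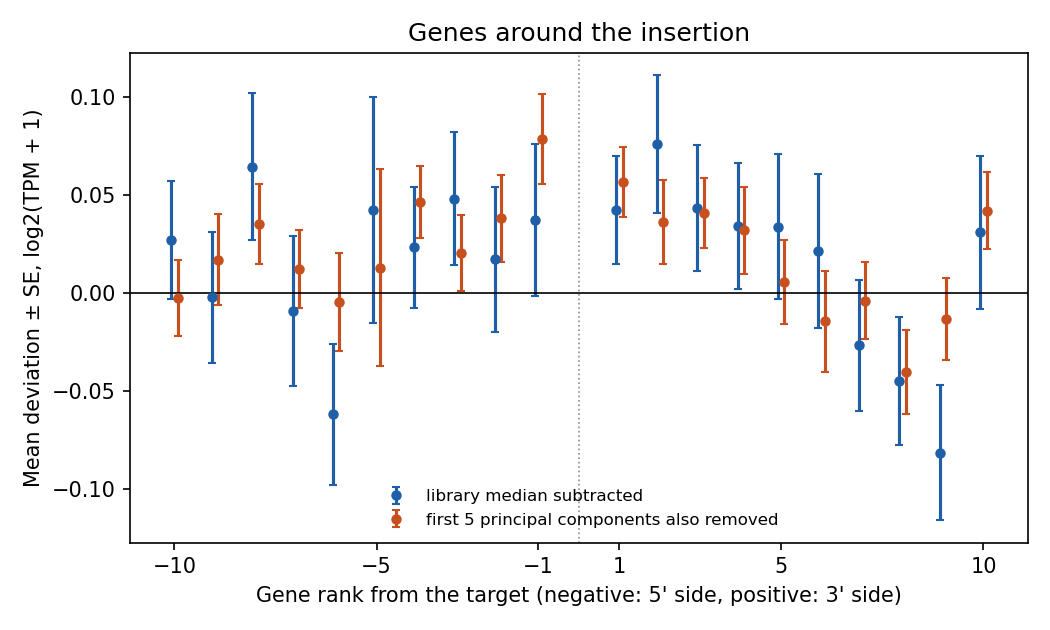
Mean deviation and standard error, as log2(TPM + 1), of the genes at ranks 1 to 10 on the 5' side (negative) and the 3' side (positive) of the target. Blue points are relative to strains of the same prefix with the library median subtracted, and orange points also have 5 principal components removed; at rank 1 the means are 0.04 and 0.08 on the 5' side and 0.04 and 0.06 on the 3' side.

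Genes that overlap the target on the other strand were described apart. The 16 such genes had a mean of -0.52 ± 0.54 and a median of -0.64, and 12 lay below 0. The lowest was APQ13 over NET1 (-1.475), chosen after its value was seen. Because strand is not known, part of these values can be reads of the target. The cassette also stands in place of an allele of the target, so sequence of these genes may be lost with it, which was not analysed.

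Neighbours on the 5' side differed by orientation. Divergent neighbours, which share an upstream region with the target, had a mean of 0.14 ± 0.47 (SD, n = 109), and tandem neighbours, which end upstream of it, had -0.07 ± 0.63 (n = 99). ANB1 and SNC1 were divergent, while SSF1, IRT1 and LTE1 were tandem, as were POL2, BDH1 and TOP2. The difference of 0.21 passed a permutation test (p = 0.0070, adjusted p = 0.026). Medians were closer, at 0.04 and -0.02. Without the 2 highest divergent and 2 lowest tandem genes, a step chosen after the values were seen, the difference was 0.13 (permutation p = 0.056), and without the 24 strains with a shifted chromosome, it was 0.18 (adjusted p = 0.084). With 5 principal components removed it was 0.13 (adjusted p = 0.0083), and the tandem mean was then 0.01 and the divergent mean 0.14. By prefix the difference was 0.28, 0.30, 0.15, 0.30, 0.13 and -0.07. On the 3' side, convergent neighbours (0.02 ± 0.39, n = 117) and tandem ones (0.07 ± 0.42, n = 95) differed by -0.05 (p = 0.40, adjusted p = 0.56).

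**Figure D3:**
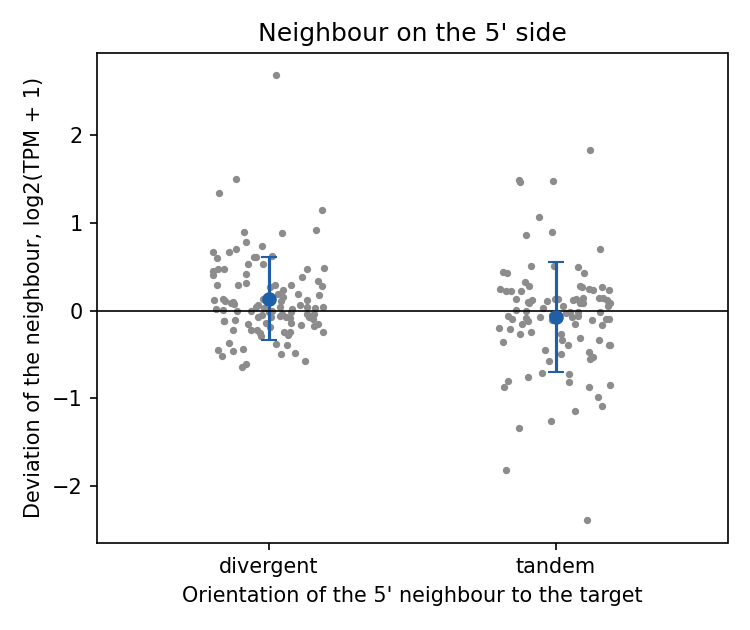
Deviation of the neighbour on the 5' side, as log2(TPM + 1), for divergent and tandem neighbours. Grey points are single strains, and blue points and bars are the mean and SD, 0.14 ± 0.47 for 109 divergent and -0.07 ± 0.63 for 99 tandem neighbours.

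Relative to strains of the same prefix, the rest of the insertion chromosome did not move as a rule. Its genes beyond 50 kb had a mean deviation of 0.01 ± 0.10 (SD, n = 238) relative to other chromosomes (sign-flip permutation p = 0.32, adjusted p = 0.54). In prefixes 1, 2 and 3 most targets lay on the same chromosome, so a change shared by their strains is largely part of the reference. The mean cannot exclude such a change. Single libraries did show shifts of a whole chromosome. Of 4256 pairs of a library and a chromosome, 33 had a median deviation beyond 0.3, a bound chosen after the values were seen, against a scaled median absolute deviation of 0.029. They comprised 28 above and 5 below, in 30 libraries of 24 strains, and 7 lay on the target's own chromosome. Chromosome XII was high in 13 libraries, among them both ACS1 libraries (0.43 and 0.46) and those of MAK16 (0.50), UBC5 (0.51) and CCT8 (0.52). Chromosome I was high in 7, with 0.92 and 0.88 in the GIP4 strain and 0.60 and 0.63 in the FUN12 strain. Chromosome III was low in 4: NUP60 (-0.98 and -0.94), MED7 (-0.86) and TAF7 (-0.47, with -0.17 on the side away from MAT). Chromosome VI was low in the RPC82 strain (-0.42).

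**Figure D4:**
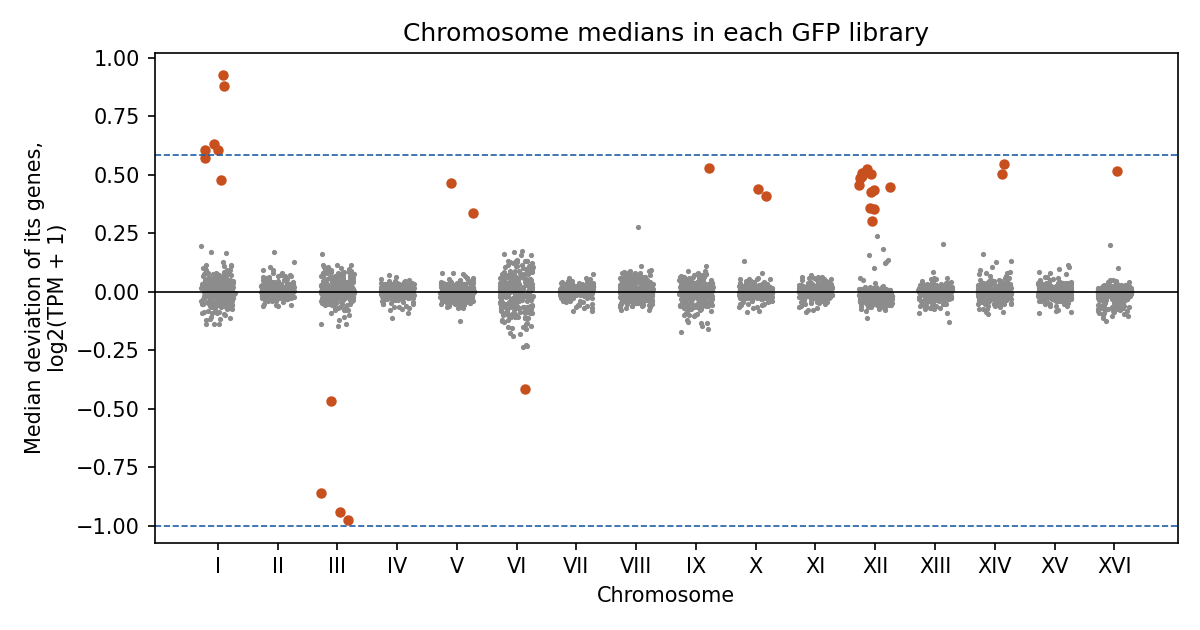
Median deviation of the genes of each chromosome, as log2(TPM + 1), in each GFP library. Each point is a library, orange points lie beyond 0.3, and dashed lines mark the log2 ratios of 3 copies over 2 (0.58) and of 1 copy over 2 (-1); 33 of 4256 points are orange.

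Mating-type transcripts, which a diploid cell represses, also set some strains apart. MF(ALPHA)1, the alpha-factor gene, was at 1387 to 2419 TPM in the libraries of NUP60, MED7 and TAF7, against a median of 1.32 TPM over the libraries, and HMRA1 was listed at 0 there, against a median of 87.6 TPM. MF(ALPHA)1 was 97.3 TPM in the CCT8 strain, where HMRA1 was at 42.9 TPM. MFA2, an a-factor gene, was at 648 to 1471 TPM in both KIN3 libraries and the SMC1 library, against a median of 5.23 TPM. In these 3 libraries MATALPHA2 was at 35.0 to 47.5 TPM, against a median of 70.5 TPM, and MATALPHA1, low in most libraries (median 0.704 TPM), was listed at 0. Mating-type genes have near-identical silent copies, so their reads can be shared. In the other libraries the highest values were 11.3 TPM for MF(ALPHA)1 and 32.9 TPM for MFA2. These strains were singled out after their values were seen.

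**Figure D5:**
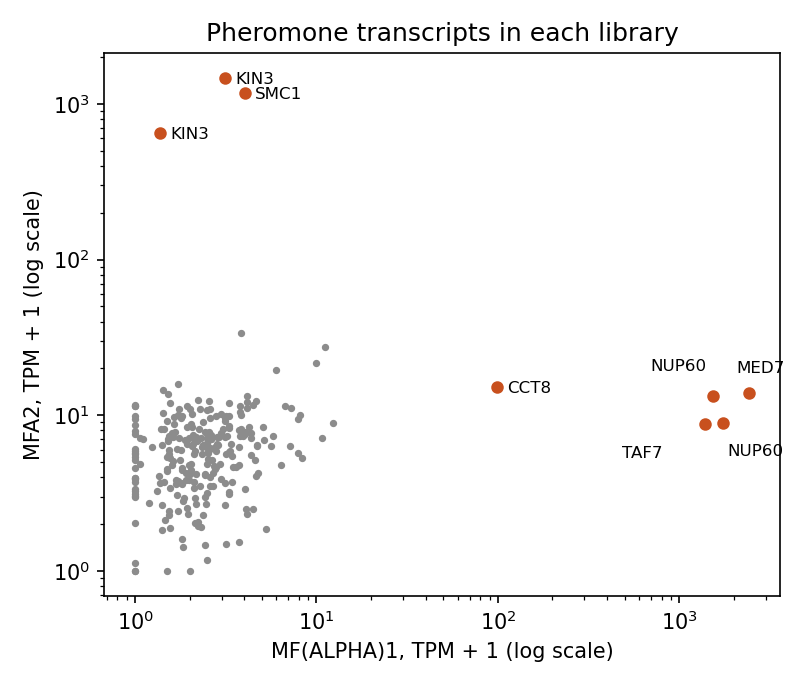
TPM + 1 of MF(ALPHA)1 and MFA2 in each library, on log axes. Each point is a library, and the orange points, with their targets, are above 50 TPM for either transcript.

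Transcripts related in function to the target were examined next. For partners in the same complex, the mean deviation was 0.18 ± 0.30 (SD, n = 35 strains), with 25 strains above 0. The highest were the small-subunit processome in the UTP21 strain (0.84, with 25 of 26 members above 0) and the RNA polymerases in the strains of their shared subunits RPB10 (0.80, 28 of 30) and RPB8 (0.71, 29 of 30). The lowest were cytochrome bc1 in the QCR2 strain (-0.30), the Sm and LSM proteins in the LSM3 strain (-0.18) and cohesin in the REC8 strain (-0.14). The mean passed sign-flip permutation (p = 0.0010, adjusted p = 0.0056), and the median over strains was 0.09. Of the 7 strains with the highest partner means, 6 had a target that counted as not lowered. These targets were UTP21 (0.66), RPB8 (-0.01), RPC82 (0.20), RPC40 (-0.32), UTP5 (-0.41) and IMP4 (-0.39). RPB10 was at -0.50 in its strain, just past the bound. All 7 belong to the RNA polymerase or the small-subunit processome list, so the mean rests largely on these lists. The other strains of these lists were RPO26 (0.24), NOP56 (0.01), NAN1 (-0.05) and RPC17 (-0.13). Whether partners in the other complexes rose was not tested apart. Several strains share a list, so they are not fully independent, and with 5 principal components removed the mean was 0.09.

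Paralogs had a mean of 0.01 ± 0.71 (n = 35, p = 0.96). The highest were CYC7, the hypoxic cytochrome c, in the CYC1 strain (1.96), CUE1 in the CUE4 strain (1.82) and RPS27B in the RPS27A strain (0.86), and the lowest were GAC1 in the PIG1 strain (-1.96), SPT23 in the MGA2 strain (-1.59) and COX5A in the COX5B strain (-0.72). Reads of near-identical copies can be shared between paralogs. Pathway partners had a mean of 0.02 ± 0.26 (n = 23, p = 0.71). Glycine cleavage and one-carbon genes in the GCV3 strain (0.56), phospholipid genes in the INO1 strain (0.30) and TCA cycle genes in the SFC1 strain (0.23) were the highest, and sulfur amino acid genes in the CYS3 (-0.60) and MET10 (-0.56) strains and polyamine genes in the SPE1 strain (-0.27) the lowest. Adjusted p was 0.96 for paralogs and 0.78 for pathways.

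Libraries of a strain resembled each other more than libraries of different strains. The mean correlation of deviations across genes, which are not independent replicates, was 0.249 for 46 pairs of a strain and 0.009 for 1603 pairs of different strains, a difference of 0.240 (one-sided permutation p = 1e-04, the smallest these permutations can give). The GIP4 (0.955), CYS3 (0.894) and CNE1 (0.867) pairs were closest, while the KIN3 pair had -0.11 and the 6 PAN5 libraries a mean of 0.098. The difference was 0.668 in prefix 1 (10 pairs) and 0.121 in prefix 6 (36 pairs, permutation p = 0.0070).

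Among the 10 prefix-1 strains with 2 libraries each, 5421 of 5983 genes differed by limma's F test (5455 at an unadjusted p under 0.05). The test sets strain means against the spread between a strain's 2 libraries, whose titles differ only in the last number. No label says whether these were separate cultures, so the count does not separate genotype from other differences between the strains. Ranges between the highest and lowest strain means are given with the residual SD of the fit. The widest were those of YDR524C-A (8.97, SD 1.49), HMRA1, the silent a1 copy (7.63, SD 0.25), and the U3 small nucleolar RNA SNR17A (7.37, SD 0.40). Next came MET17, homocysteine synthase (7.17, SD 0.32), DDR2, a stress gene (6.66, SD 0.55), RME2 (6.62, SD 1.58) and TAR1 (6.52, SD 1.72). AFB1, an a-factor barrier gene, spanned 6.20, COX4 6.11, YNL194C 5.86, the alpha-agglutinin gene SAG1 5.70 and YPR145C-A 5.58. HMRA1, AFB1 and SAG1 are mating-type genes, and the NUP60 and KIN3 strains with haploid transcripts are among the 10. ACS1, FUN12, GIP4 and NUP60, each with a shifted chromosome in both libraries, are among them too. The range of MET17 includes KIN3, LTE1 and RBG1, where it was below 1 TPM.

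In prefix 6, PAN5 was the only gene that differed between its own strain and the other libraries (log2 fold change -0.85, SE 0.12, limma adjusted p = 7.5e-05, 661 genes at an unadjusted p under 0.05). PAN5 encodes ketopantoate reductase. For the NNF2, SWH1, TRM13 and FRS2 strains limma called 0 genes, against 579, 50, 91 and 105 at an unadjusted p under 0.05. These unadjusted counts depended on single libraries. For PAN5 the count was 1020 without library 1, 204 without library 2, 166 without library 3 and 363 without library 4, and for NNF2 it was 984 without library 1 and 382 without library 4. It was 23 for SWH1 without library 4, 234 and 32 for TRM13 without libraries 1 and 3, and 24 and 227 for FRS2 without libraries 1 and 2. Adjusted calls became 3 and 2 for PAN5 without libraries 1 and 6, 1 for NNF2 without library 1 or 2, 1 for TRM13 without library 1, and 1 each for SWH1 and FRS2 without YTH1 library 2 (69 and 164 unadjusted). Some of these libraries had a shifted chromosome that others of their strain lacked: XII in PAN5 libraries 2 (0.30) and 3 (0.44) and in FRS2 libraries 1 (0.48) and 3 (0.36), and I in SWH1 library 4 (0.60). Ribosome biogenesis genes had medians of -0.35 in PAN5 (0 of 80 above 0), 0.37 in NNF2 (80 of 80) and 0.31 in TRM13, and environmental stress genes had -0.67 in NNF2 and 0.31 in SWH1 (44 of 45 above 0). Adjusted over the list alone, 6 stress, 4 sulfur amino acid, 3 chaperone, 2 TCA cycle genes and 1 fatty acid gene fell in NNF2, and 1 chaperone gene rose in PAN5. For these lists adjusted p was 0.69 or higher with an estimated correlation. Array weights raised the calls to 769 in PAN5 and 1293 in NNF2.

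Strains whose targets belong to the transcription machinery (14 targets) differed from other strains in 739 of 5969 genes by limma, 554 higher and 185 lower. The targets of the class were left out of this count. Chance could not be excluded for it. Of 100 splits of the strains into groups of the same sizes, the real one included, 5 gave as many genes or more. Without the 24 strains with a chromosome shift, which include the class members MED7, TAF7, RPC82 and BDP1, 0 genes were called (1006 unadjusted). In the full set ribosome assembly genes rose (adjusted p = 0.40 with an estimated correlation for the ribosome biogenesis list), led by NOG1 (0.95, SE 0.21), ARX1 (0.90), RRS1 (0.81), RRP12 (0.80) and ALB1 (0.78), together with SFG1 (0.90), the iron oxidase gene FET3 (0.89), SAG1 (0.83), SAP185 (0.79), DUS1 (0.79), HMT1 (0.77) and RFU1 (0.77). SNR17A fell the most (-1.97, SE 0.57), followed by YRF1-7 (-1.44), HMRA1 (-1.28), YNR034W-A (-1.18), the glyceraldehyde phosphate dehydrogenase gene TDH1 (-0.996), STF2 (-0.98), YPT53 (-0.91), STF1 (-0.85), YJR037W (-0.83), TSA2 (-0.81), UGX2 (-0.81) and YER188W (-0.79). SAG1, a mating-type gene, turned to just below 0 without the chromosome-shift strains, which include MED7 and TAF7. YRF1-7 belongs to a family of near-identical subtelomeric genes and is uncertain. RPC82, a target of the class, was also higher (0.42). At an unadjusted p under 0.05 there were 1623 genes. With library medians subtracted, which moved the median of all genes from 0.05 to -0.01, the split was 412 higher and 426 lower.

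By list, 71 of 80 ribosome biogenesis genes rose (77 adjusted over the list alone; SSF1 0.72), as did 21 of 137 ribosomal protein genes (26 adjusted over the list alone; RPS28B 0.56, RPS9A 0.47, RPL21A 0.42, RPL6B 0.38). For these lists adjusted p = 0.40 and 0.85 with an estimated correlation, and their medians were 0.51 and 0.15, or 0.45 and 0.08 with library medians subtracted. Haploid-specific genes rose in 4 of 5 cases (4 adjusted over the list alone, with STE4 0.73, FAR1 0.60, GPA1 0.60, SST2 0.57), and MF(ALPHA)2 also rose (1.05). MED7 and TAF7, the strains with haploid transcripts, are in this class. Without the chromosome-shift strains, which include both, GPA1 and SST2 turned to just below 0. Of 17 glycolysis genes 7 fell (10 adjusted over the list alone; ENO1 -0.45, TDH2 -0.34, GPM1 -0.34). Adjusted p = 0.71 for haploid-specific genes and 0.40 for glycolysis with an estimated correlation. In the ergosterol list 6 of 25 rose and 2 fell (12 and 2 adjusted over the list alone; ERG5 0.47, ERG11 0.47, ERG25 0.43, ERG1 0.42), in the iron list 5 of 23 rose (6 adjusted over the list alone; SIT1 1.13, FIT2 0.86, FTR1 0.57) and in amino acid biosynthesis 5 of 49 rose (5 adjusted over the list alone; LEU9 0.34, LYS4 0.32, ARO7 0.32, ILV2 0.31). For these lists adjusted p = 0.71, 0.73 and 0.94 with an estimated correlation. Their medians were 0.14, 0.20 and 0.07 (35 of 49 amino acid genes above 0), or 0.07, 0.14 and 0.003 (25 of 49) with library medians subtracted. Stress, respiratory chain and chaperone genes had 1 call each (GRX1 -0.49, COX12 -0.28, SSE1 0.22; 1, 0 and 0 adjusted over the list alone), with adjusted p = 0.71, 0.71 and 0.94 with an estimated correlation. Their medians were -0.32 (2 of 45 above 0), -0.14 (10 of 40) and -0.06 (10 of 26), or -0.38 (0 of 45), -0.20 (5 of 40) and -0.12 (9 of 26) with library medians subtracted, so the chaperone median and SSE1 differ in sign. RPS28B, RPS9A, RPL21A, LYS4, ARO7 and SSE1 no longer passed with library medians subtracted. With 5 principal components in the model, RPS28B and ENO1 turned sign.

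No camera call in any comparison held with an estimated correlation. For the transcription machinery class fry gave adjusted p = 0.0027 for ribosome biogenesis, 0.014 for haploid-specific genes and glycolysis and 0.029 for ergosterol. Lists without a call in this class had medians of -0.12 (TCA cycle), -0.06 (fatty acid oxidation), 0.04 (hexose transport), -0.05 (sulfur amino acids), -0.01 (purines), 0.10 (phosphate), 0.01 (histones), -0.10 (haploid a-specific), 0.07 (meiosis) and -0.05 (auxotrophic markers); hexose transport and histones changed sign with library medians subtracted. Leaving out the 6 strains with mating-type transcripts gave 218 calls. With 5 principal components in the model, 0 genes were called (563 unadjusted).

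For the ribosome (18 targets), splicing (11 targets) and mitochondrion (24 targets) classes limma called 0 genes, against 240, 18 and 77 at an unadjusted p under 0.05. In the ribosome class ribosome biogenesis genes had a median of 0.14 (68 of 69 above 0), ribosomal protein genes 0.12 (130 of 134) and stress genes -0.22 (1 of 45), and 1 auxotrophic marker and 1 sulfur amino acid gene fell when adjusted over the list alone. In the splicing class stress genes had a median of 0.29 (43 of 45 above 0) and sulfur amino acid genes 0.17 (25 of 27), or 0.24 (42 of 45) and 0.12 (23 of 27) with library medians subtracted. TCA cycle genes had 0.18 (19 of 21), ribosome biogenesis genes -0.09 (7 of 80) and ribosomal protein genes -0.06 (15 of 137), or 0.13 (18 of 21), -0.14 (2 of 80) and -0.11 (1 of 137) with library medians subtracted. In the mitochondrion class, where 1648 of 5960 genes lay above 0 (median -0.04), respiratory chain genes had 0.05 (26 of 37) and iron genes -0.13 (1 of 23); with library medians subtracted these were 0.096 (34 of 37) and -0.083 (2 of 23). Ribosome biogenesis genes had -0.11 there (3 of 80), or -0.06 (15 of 80), and ribosomal protein genes had -0.003 (65 of 137), or 0.05 (113 of 137). For these lists adjusted p was 0.55 or higher with an estimated correlation.

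The wild-type library lay furthest from the median of the GFP strains in stress, ribosome biogenesis and hexose transport genes, yet GFP libraries lay as far in each list, and with 1 library there is no test. Environmental stress genes had a median difference of -1.95, and 6 of 266 GFP libraries set against the other strains were as low or lower (down to -3.38). Ribosome biogenesis genes had 0.77, and 20 were as high or higher (up to 1.35). Ribosomal protein genes had 0.40 (36 as high), respiratory chain genes -0.48 (28 as low), chaperones -0.56 (33 as low) and hexose transport -0.67 (38 as low), and for the other lists 33 to 112 GFP libraries lay as far the same way. With library medians subtracted these numbers were 4 for stress, 32 for ribosome biogenesis, 40 for ribosomal proteins, 14 for the respiratory chain, 6 for chaperones, 20 for hexose transport and 17 to 126 for the others. As a description of this library alone, list medians were also placed among 10000 random lists matched on expression, which ignores that genes of a list vary together. Stress genes were at percentile 0, ribosome biogenesis and ribosomal protein genes at 100, respiratory chain genes at 0, chaperones at 0.01, hexose transport at 0.03, the TCA cycle (-0.49) at 0.27, phosphate (-0.48) at 0.39, glycolysis (-0.22) at 1.75 and purines (0.30) at 97.6. The other lists lay between percentiles 9.61 and 85.1: ergosterol 0.14, auxotrophic markers 0.40, amino acid biosynthesis 0.07, sulfur amino acids -0.13, iron -0.15, fatty acid oxidation -0.23, histones 0.19, haploid a-specific -0.15, haploid-specific -0.07 and meiosis -0.03.

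Single genes outside the range of all GFP libraries numbered 62, with 40 above and 22 below; with library medians subtracted there were 84, 28 above and 56 below. A GFP library set against all the others had a median of 12 such genes (0 to 1031), and 55 had 62 or more. URA1, dihydroorotate dehydrogenase, was the highest (1390 against 109 TPM, 3.67), with YPR053C (2.44), URA4 of the same pyrimidine pathway (2.05), RIB4 (1.81), YPL044C (1.65), YHL006W-A (1.55), SSU72 (1.52), the uracil permease gene FUR4 (1.478), CDC45 (1.39) and YER107W-A (1.27). YNL194C was the lowest (-4.81), with the heat shock genes HSP12 (-4.76) and HSP26 (-4.06), IGD1 (-3.99), AFR1 (-2.56), FRT2 (-2.46), YDR510C-A (-2.41) and the polyubiquitin gene UBI4 (-2.33); YPR145C-A (-3.90) and YJR037W (-3.51) were listed at 0. RPL5, whose promoter drives the cassette, lay inside the range of the GFP libraries, at 4296 TPM against a median of 3069 TPM (1488 to 5399). Also inside the range were HIS3 at 61.0 against 46.1 TPM (26.5 to 96.3), LYS2 at 12.8 against 11.1 (0 to 24.2) and MET17 at 66.4 against 45.3 (0 to 230.5). URA3 and LEU2 were listed at 0 in every library.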

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

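The test of the difference between prefixes was chosen only after the result was seen. In the SWH1 strain, library 2 had 6.12% of its TPM in ribosomal DNA transcripts, while the other 3 libraries lay between 7.46% and 7.73%, a gap just past Dixon's critical value for 4 samples. It was the only 1 of 24 such checks in the NNF2, PAN5 and SWH1 strains to pass. The checks took the lowest and the highest value of each measure, and among so many a single pass can arise by chance.

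Libraries of a strain were closer to each other in prefix 1 than in prefix 6. The mean correlation of a strain's libraries was 0.676 in prefix 1 and 0.151 in prefix 6, a difference of 0.5256 (permutation p = 0.0009, adjusted p = 0.0009). No cause was tested, since no label says what a prefix marks or whether a strain's libraries came from separate cultures. The titles do differ in their middle part, a letter and a number. A strain's libraries share it in prefix 1 and differ in it in prefix 6. The difference between the prefixes cannot be separated from this difference in the titles. Chromosomes of the targets also largely differed between these prefixes. The target level and the divergent minus tandem difference did not differ between any of the 15 pairs of prefixes (lowest adjusted p = 0.65 and 0.84).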

How the results depend on the processing

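The alternatives that leave out strains with mating-type transcripts, with a chromosome shift or with over 20% ribosomal DNA, or that leave out YTH1 library 2, were chosen after seeing the data. Of the alternatives to the main comparisons, 245 kept the direction and the side of the threshold or stayed within 1.5 times the count, 30 moved, 7 reversed, 6 became stronger and 1 weaker. For single genes named among many, 1733 were the same, 144 weaker, 88 moved and 7 reversed. Except where stated, the cause was not tested.

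The relation of target level against expression became stronger with a pseudocount of 0.1 (r = 0.202), a median TPM of 20 or more (0.170) and chromosome-shift strains left out (0.176), and reversed with a pseudocount of 5 (-0.038). With the library median not subtracted, the adjacent gene on the 5' side reversed (-0.0018), as did paralogs (-0.044) and pathway partners (-0.00077). With 5 principal components removed, the 5' side was 0.078, the 3' side 0.057, adjacent genes beyond 3 SD numbered 16, the distance profile had 15 calls, and paralogs reversed (-0.052). Reference strains of all prefixes gave 7 adjacent genes beyond 3 SD and 1 call in the distance profile, as did a pseudocount of 5 and a TPM minimum of 20 (1 call each). Chromosome-shift strains left out weakened the divergent against tandem difference (0.176) and reversed the insertion chromosome (-0.0021), which by construction removes strains with a shift there; paralogs reversed without prefix 6 (-0.018).

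In the PAN5 comparison, genotype as a factor gave 3 genes, array weights 769, and leaving out a replicate 1 to 3. NNF2 gave 1, 1293 and 0 to 1, SWH1 1, 5 and 0 to 0, TRM13 1, 5 and 0 to 1, and FRS2 1, 9 and 0 to 0. SWH1 and FRS2 also gave 1 gene with no filter, with the library median subtracted and with YTH1 library 2 left out. The ribosome class gave 3 genes with prefix and 5 principal components. The transcription machinery class gave 0 genes with prefix and 5 principal components, 218 without mating-type shifted strains and 0 without chromosome-shift strains, which leaves out 4 of its 14 members. In that class, YNR034W-A (0.22), RPS28B (-0.035), ENO1 (0.013) and RPC82 (-0.018) reversed with 5 principal components, and SAG1 (-0.036), GPA1 (-0.053) and SST2 (-0.015) with chromosome-shift strains left out. The F test of prefix-1 strains gave 5203 to 5507 genes with a library left out, where the lone sample is assumed to vary like the other strains. With the title suffix as a replicate block it gave 5378 against 5421. The numbers were not shown to pair libraries, and the block is no measure of effect size. Depth is known only as aligned bases, so counting error per gene could not be given; the BNA6 library was the shallowest, with 519 megabases.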

Other observations

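All tests of explanations in this part were chosen only after the results were seen.

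Transcripts of 2 marker genes were lost in some strains, a pattern picked after the values were seen. MET17, the homocysteine synthase gene (XII:732542-733876), was below 1 TPM in 20 libraries of 17 strains, with 0.192 TPM the highest among them and 6.96 TPM the lowest elsewhere. KIN3, LTE1 and RBG1 were the 3 of these strains with 2 libraries, and both libraries were low in each. LYS2, a lysine synthesis gene, was below 1 TPM in the NOP56, RPS27A and RQC1 strains (highest 0.483 TPM, lowest elsewhere 6.38 TPM). BY4743 is heterozygous at both loci, and DNA was not analysed here.

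In 2 strains the transcript of a neighbour moved while that of the target did not fall, again picked after the values were seen. DED1 was at -1.25 in the GEP3 strain, where GEP3 was at 0.01, and POL2 was at 1.83 in the ORC5 strain, where ORC5 was at 0.29. Apart from these, SMX3 (0.72) and DPM1 (0.36), the targets of 2 other strains, are adjacent genes, and neither was lowered in its own strain.

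The first pattern is the 33 pairs of a library and a chromosome with a median deviation beyond 0.3. All 33 stayed beyond 0.3 after a regression on GC content, gene length and expression, which argues against those biases, and 26 lay on a chromosome without the target, which argues against an effect of the insertion there and leaves the 7 on the target's own chromosome open. In 30 pairs both sides of the chromosome midpoint were beyond 0.2 in the same direction, the exceptions being INO1 (V), TAF7 (III) and BDP1 (X). A changed copy number of the whole chromosome may account for pairs among those 30, but their size and evenness varied. Gains ran from 0.30 (PAN5, XII) to 0.92 (GIP4, I), beside the 0.58 that 3 copies over 2 would give. Losses ran from -0.42 (RPC82, VI) to -0.98 (NUP60, III), beside -1 for 1 copy over 2. The 2 sides of chromosome I were uneven in the GIP4 libraries (0.52 and 0.99, 0.30 and 0.88) and in NAN1 (0.58 and 0.22). Only RNA was measured, so a changed copy number is a hypothesis.

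The second pattern is the mating-type transcripts. In the NUP60 and MED7 libraries both sides of chromosome III had medians of -0.81 or lower, consistent with the loss of a copy carrying MATa. In the TAF7 library the side that holds MAT was also at -0.81 but the other at -0.17 (scaled median absolute deviation over libraries 0.054), which argues against loss of a whole copy and leaves loss of the MAT side alone open. The KIN3 and SMC1 libraries had -0.116 as the lowest median on the MAT side, in SMC1, whose other side was at 0.27; this argues against a lost chromosome in these strains, while the uneven sides in SMC1 and loss of heterozygosity at MAT were not tested. Haploid cells carrying the insertion would lack the target, while the lowest target deviation in these 5 strains was -1.17, which argues against that explanation.

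The third pattern is ANB1 at 2.69 in the strain inserted at CYC1 beside it, and whether the insertion acted on ANB1 alone or ANB1 moved with other oxygen-regulated genes cannot be told apart, since listed genes went both ways. A list of 19 such genes, written after ANB1 had been seen, had 17 measured members with a median of 0.275 in this strain; 11 were above 0 (TIR1 2.17, CYC7 1.96) and others below (NCP1 -0.39, ERG11 -0.28). ANB1 lay 2.84 SD above its line on the list median over the other strains, but a line on the median of members going both ways was taken to decide nothing, a condition added after the 11 of 17 were known. A set of 7 genes, tried first and picked after their values were seen (median 1.23, ANB1 0.65 SD from its line), bears on neither explanation, since the choice fixed its outcome. ANB1 was as high in 4 strains inserted elsewhere: TIF35 (2.95), YEF3 (2.79), TAZ1 (2.75) and DPM1 (2.70).

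For limma comparisons, 100 splits of the samples into groups of the same sizes, the real one included, were fitted. The median of the other splits was 0 genes in each comparison. Chance could not be excluded for the 739 genes of the transcription machinery class, where 5 splits gave as many or more and the highest other gave 1748, nor for the count of 1 gene in the PAN5 comparison, where 8 splits gave 1 gene or more and the highest other gave 1593. That count bears on any gene and not on PAN5 itself, the target of the strain, which lay below 0 in all 6 libraries (-1.37 to -0.38, limma adjusted p = 7.5e-05). A split with 1593 genes against 1 points to some structure of the prefix-6 libraries, but what set that split apart was not tested. Where the real split called 0 genes, all 100 splits necessarily give as many, so the count says nothing about chance; the highest other was 2025 for NNF2 and SWH1, 2382 for TRM13 and FRS2, and 1911, 2824 and 1 for the ribosome, splicing and mitochondrion classes.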
